A study of Mus musculus with 6 samples.

How the data were processed

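Gene expression was measured by RNA sequencing in 6 libraries labelled as left ventricle of male C57BL/6J mice, 3 from mice given PBS and 3 from mice given L-proline. Both groups carried a model of heart failure with preserved ejection fraction (HFpEF) made with a high-fat diet and L-NAME, an inhibitor of nitric oxide synthases. Per the labels' protocols, polyadenylated RNA was selected, libraries were made with a NEBNext Ultra kit from 1.5 µg of RNA, and paired-end reads were taken on a NovaSeq. The submitters' processing notes name HISAT2, HTSeq 0.13.5 and the mouse build GRCm39, without saying which step each served. Group and replicate number were taken from the sample titles. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be partly technical.

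The authors deposited 1 table of FPKM values (fragments scaled to gene length and library total), per the file headers, with 6 columns and 14408 gene symbols, none duplicated. FPKM is already scaled to library size and gene length by the authors, so a gene's value depends on the library's other abundant genes and on the gene model used. How the listed genes were chosen is not given in the sources used here. A table of mouse genes for assembly GRCm38.p6 was used only for names and older symbols, and 14145 of the symbols matched it. No coordinates are printed because that assembly is not the one in the processing notes. GC content came from the longest transcript per symbol in the GENCODE M21 transcripts.

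The FPKM values turned out to be whole multiples of the value of 1 fragment. Library totals were solved from the 13 mitochondrially encoded genes, whose values then lay within 2.03e-05 of a whole number of fragments, and each gene's length was the smallest whole number that made its 6 values whole within a tolerance of 0.01. This gave whole fragments for 14407 of 14408 genes. Totals ran from 34990473 to 37498030 fragments per library, so 1 fragment on a gene of 1 kb was worth 0.0267 to 0.0286 FPKM. A gene of that length seen in 0 fragments could still lie at up to 0.0800 to 0.0857 FPKM, the value of 3 fragments, counting error only. On simulated tables with known totals the same steps found 6 of 6 library totals and 99.1% of 1000 simulated genes exactly.

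Differences between L-proline and PBS were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided). Genes with a mean FPKM of at least 1 over the 6 libraries were tested, with Benjamini-Hochberg adjustment over them and a threshold of 0.05. Fold changes on that scale understate the change of genes with low values. Values in the text are mean FPKM ± SD with n = 3, and the error of a log2 fold change is its standard error. A looser set, unadjusted p under 0.05 with at least a 2-fold change, was also counted. There are 35 gene lists and 19 lists of cell type markers, all fixed before the data were examined, as were the tests and the alternatives except where stated otherwise. Lists with at least 5 tested members were tested with limma's camera (inter-gene correlation preset at 0.01, two-sided, Benjamini-Hochberg over 34 lists). Each list also got a score per library, the mean log2(FPKM + 1) of its tested members, compared by an exact permutation test; with 3 libraries against 3 the smallest p such a test can give is 0.1.

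The genes named are the 10 with the largest increase and the 10 with the largest decrease among those past the threshold whose 3 L-proline values all lay on the same side of the 3 PBS values, leaving out predicted models and pseudogenes. Added to these are 25 genes tied to the study's subject and, for each list described, up to 4 tested members with the smallest unadjusted p. Other genes are said to have been chosen after their values were seen, apart from members of the marker lists, which are named for their levels. Some genes that the rule names are not reported here. "Rose" and "fell" are used for genes past the threshold.

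On values simulated from the real means and library totals, limma recovered 36.0% of 50 genes changed 1.25-fold and 100% of 50 genes at each of 1.5-fold, 2-fold and 4-fold, with 5.71% of its calls false, among 10514 genes tested. Every simulated gene had the same dispersion, 0.00661, so more variable genes are recovered less often than this. Cenpf, for example, missed the threshold at a log2 fold change of -1.04 ± 0.32 (limma, adjusted p = 0.0557). A gene that did not pass may thus have changed by more than 1.5-fold. Camera found a list shifted by 0.5 on the log2 scale and called a mean of 0.05 lists in 20 shuffles of the simulated values. The simulated genes were drawn independently, so this does not show how often camera calls falsely where genes of a list move together. In the real libraries the estimated correlation was 0.25 for the interferon list, 0.47 for the ATF4 list and 0.81 for ribosomal proteins. Alternatives covered the pseudocount, the filter, scaling between libraries (median-of-ratios, quantile, equal sums, and leaving out the mitochondrial and the 20 most abundant genes), the variance model, sample weights, a replicate block, and leaving out each library. For lists they covered an estimated correlation, fry, ranks and the block. A fit of the recovered fragments with voom was chosen after the values had been seen to be whole. Random lists and simulations used fixed seeds; the fragments, GC content and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.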

Results

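RNA from left ventricle, as labelled, was profiled in mice with a diet-induced form of HFpEF to learn how L-proline alters the transcriptome, with ferroptosis (iron-dependent cell death by lipid peroxidation) and the nuclear receptor PPARγ as the stated interest. Male C57BL/6J mice, 8 weeks old at the start, received a high-fat diet with L-NAME at 0.5 g/L for 8 to 12 weeks. They were then given L-proline at 300 mg/kg per day or PBS by intraperitoneal injection for 4 to 8 weeks, and 3 libraries were made per group. Library totals recovered from the FPKM values were 37498030, 35925065 and 36709614 fragments for PBS 1, 2 and 3, and 36714388, 34990473 and 36778787 for L-proline 1, 2 and 3. Pairs of libraries within a group differed by more than the counting noise of fragments, with a chi-square per degree of freedom between 8.08 and 81.8, a spread that may be technical.

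Most heart muscle transcripts lay close to 0 in all 6 libraries, which argues against whole ventricle with its muscle as the source of the RNA. The labels and values do not settle whether the RNA came from part of the tissue or from cells in culture. The differences between groups may therefore not be those of heart muscle. The galectin gene Lgals1 stood at 3358 ± 314 FPKM in PBS and 3365 ± 347 in L-proline, vimentin (Vim) at 2871 ± 79.0 and 2328 ± 72.5, and fibronectin (Fn1) at 1374 ± 28.6 and 1328 ± 20.96; these 3 genes were chosen after their values were seen. Of 13 cardiomyocyte markers, 6 were listed and 2 had a mean of at least 1 FPKM. The sarcomere genes Ttn, Ryr2, Myl2 and Tnni3 did not exceed 0.212 FPKM in any library, and Ttn was backed by 10 to 38 fragments per library. Myh6, Myl3, Actc1, Pln, Mybpc3 and Actn2 were not listed in the table used here. Cardiac troponin T (Tnnt2) was 32.0 ± 0.777 in PBS and 14.5 ± 1.51 in L-proline, a log2 fold change of -1.09 ± 0.09 (limma, adjusted p = 0.000326), and the cardiac transcription factor Nkx2-5 was 3.43 ± 0.232 and 3.34 ± 0.308. The median over listed members was 27.2 FPKM for fibroblast markers, 39.3 for pericyte and smooth muscle markers, 0.323 for endothelial markers and 0.118 for macrophage markers. Within the pericyte and smooth muscle list the actin gene Acta2 was 850.2 ± 51.6 and 826 ± 85.95, while the smooth muscle myosin gene Myh11 was 0.0247 ± 0.0193 and 0.0207 ± 0.00410, and Rgs5 and Vtn had group means of at most 0.0961. The endothelial genes Pecam1 and Cdh5 had means over all libraries of 0.0371 and 0.136 FPKM.

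**Figure D1:**
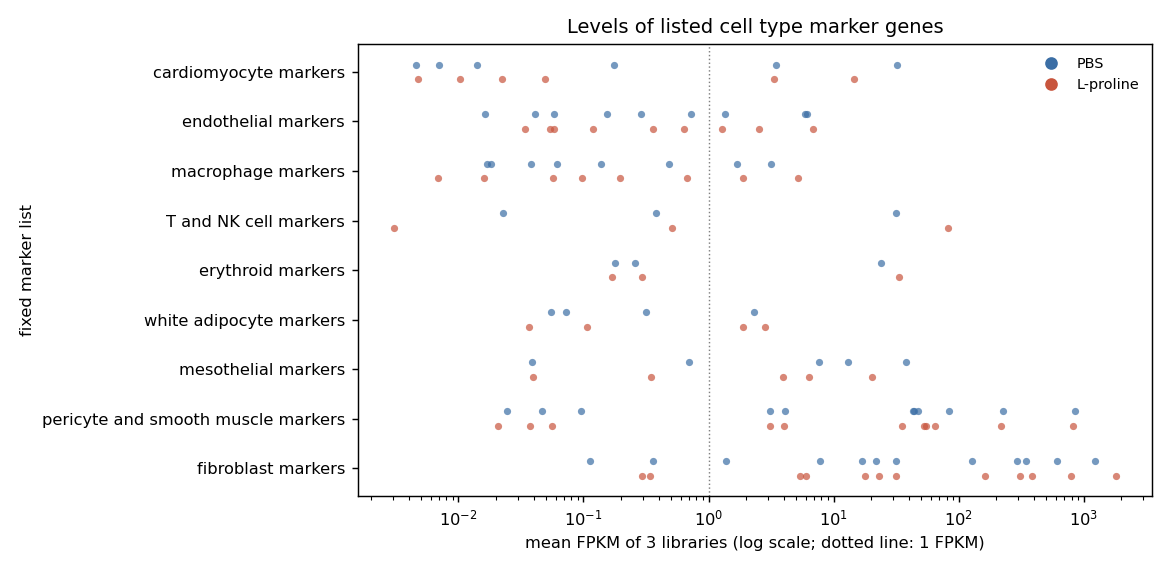
Mean FPKM (log scale, 3 libraries per point) of every listed member of 9 fixed marker lists, in PBS and in L-proline; the dotted line marks 1 FPKM. Of the cardiomyocyte markers 2 lie above the line, against 10 fibroblast markers by their mean over all 6 libraries.

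L-proline was accompanied by a broad change in which interferon-induced genes and genes of the amino acid response controlled by ATF4 stood out among the increases. Ifit3, an interferon-induced antiviral gene, went from 16.9 ± 1.24 to 127 ± 13.6 FPKM, and Trib3, a pseudokinase gene induced by ATF4, from 1.52 ± 0.354 to 19.3 ± 5.78. Genes with the largest decreases included Sprr1a, a cornified envelope gene (9.93 ± 1.03 to 1.26 ± 0.425), the lubricin gene Prg4 (18.3 ± 2.68 to 2.97 ± 0.432) and the matricellular gene Ccn2 (46.4 ± 7.75 to 11.2 ± 4.38). With limma, 2056 of 10500 genes passed, 788 higher and 1268 lower in L-proline, and 146 of these changed at least 2-fold, 85 up and 61 down. At an unadjusted p under 0.05 with at least a 2-fold change there were 147 genes, 85 up and 62 down. This looser count was higher with a smaller pseudocount and with voom, as given in a later section. The groups did not overlap for 40.1% of genes, against 10% by chance. The first principal component held 61.9% of the variance and had all PBS libraries on one side and all L-proline libraries on the other. Correlations across genes, which are not independent replicates, were 0.983 to 0.997 within groups and 0.969 to 0.986 between them.

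Limits of these counts lie in scaling, in sample weights and in single libraries. Median-of-ratios scaling gave 1003 higher and 966 lower, quantile normalization 1079 and 1015, equal sums 674 and 1676, and sample weights 1798 and 2873. Without PBS 1 the count was 976 (392 higher, 584 lower), without PBS 3 it was 874 (366 higher, 508 lower), and without PBS 2 592 were higher and 843 lower.

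Of 27 tested interferon response genes, 25 rose and 0 fell, 26 and 0 when adjusted over the list alone. Besides Ifit3, Ifit1 went from 18.7 ± 1.22 to 104 ± 16.5 FPKM and Usp18, which removes the ubiquitin-like ISG15 from proteins, from 17.3 ± 2.05 to 82.9 ± 1.31. Isg15 itself rose from 58.7 ± 9.18 to 280.1 ± 21.5, and Dhx58, a sensor related to RIG-I, from 9.69 ± 0.612 to 35.7 ± 2.10. The mean log2 fold change of the list was 1.32, and its score rose from 3.82 ± 0.0970 to 5.14 ± 0.0814 (exact permutation p = 0.1, the smallest possible). Camera gave an adjusted p = 1.98e-29 with the preset correlation and an adjusted p = 0.153 with an estimated correlation. Ifit3b, at 4.71 ± 0.672 and 34.9 ± 6.70 FPKM, is a near copy of Ifit3, so the division of fragments between these is uncertain. Macrophage markers were low, with Cd68 at 3.17 ± 0.536 and 5.19 ± 0.297 FPKM (log2 fold change 0.57 ± 0.11, adjusted p = 0.0101).

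In the ATF4 and amino acid response list, 17 of 25 tested genes rose and 0 fell, 20 and 0 adjusted over the list alone. Mthfd2, a mitochondrial folate enzyme, went from 10.5 ± 0.738 to 39.2 ± 4.61 FPKM, Chac1, which degrades glutathione, from 5.61 ± 0.219 to 23.2 ± 3.28, and asparagine synthetase (Asns) from 13.6 ± 0.901 to 43.4 ± 6.01. Trib3 had the largest log2 fold change of all named genes, 2.98 ± 0.21 (adjusted p = 0.000225). The mean log2 fold change was 0.87, with a camera adjusted p = 1.79e-17 and an adjusted p = 0.326 with an estimated correlation.

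Some histone transcripts also rose. The fixed list drawn up for RNAs without a poly(A) tail had 5 tested members, all histone genes. All 5 rose, 5 also when adjusted over the list alone. Whether these transcripts lacked a tail was not measured, and the libraries were made from polyadenylated RNA. H2bc4 went from 39.3 ± 3.19 to 103 ± 1.01 FPKM, H1f2 from 79.3 ± 10.03 to 135 ± 22.2, H1f3 from 1.249 ± 0.229 to 4.73 ± 1.46 and H4c8 from 1.48 ± 0.746 to 4.27 ± 0.350. H2bc18, among the 10 largest increases, went from 1.04 ± 0.616 to 8.36 ± 0.186. The camera adjusted p was 1.44e-05, and 0.153 as an adjusted p with an estimated correlation. All 5 tested members had PBS means above 1 FPKM, the lowest being H1f4 at 1.15. With no filter, which adds members at lower levels, the median log2 fold change of the list went from 1.13 to 0.63. Histone genes have near-identical copies, so the assignment of fragments to single genes is uncertain.

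Among p53 and apoptosis genes, 8 of 21 rose and 3 fell, 9 and 3 adjusted over the list alone. The cell cycle inhibitor gene Cdkn1a went from 244 ± 10.4 to 377 ± 34.1 FPKM, the receptor gene Eda2r from 7.71 ± 1.01 to 17.1 ± 4.95, and the stress gene Sesn2, also on the ATF4 list, had a log2 fold change of 0.72 ± 0.10. Camera gave an adjusted p = 0.00107, and an adjusted p = 0.181 with an estimated correlation. Of 45 ribosomal protein genes, 8 rose, 0 fell and 37 did not pass, with 19 rising and 0 falling when adjusted over the list alone, led by Rps19 at a log2 fold change of 0.32 ± 0.07 (camera adjusted p = 1.06e-09; adjusted p = 0.826 with an estimated correlation). The median log2 fold change of the ribosomal list was 0.19, and 0.07 with quantile normalization (camera adjusted p = 0.0185; 9.57e-13 to 0.826 over the alternatives). Among nuclear genes of oxidative phosphorylation, 8 of 77 rose and 3 fell, 4 and 1 adjusted over the list alone (camera adjusted p = 0.00225; adjusted p = 0.852 with an estimated correlation). Quantile normalization ended the call of the oxidative phosphorylation list (adjusted p = 0.135).

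Some genes of glycolysis, the hypoxia response and the cell cycle fell and none rose, and these lists passed with the preset correlation but not with an estimated one. Of 19 glycolysis genes, 9 fell and 0 rose, 12 and 0 adjusted over the list alone; muscle-type phosphofructokinase (Pfkm) went from 44.3 ± 0.882 to 28.5 ± 1.75 FPKM, Gpi1 from 316 ± 17.1 to 214 ± 20.2, and Pgk1 had a log2 fold change of -0.58 ± 0.09. Of 20 hypoxia response genes, 10 fell and 0 rose, and adjusted over the list alone 11 fell and 1, Ddit4, rose. Pdk1, a kinase that inhibits pyruvate dehydrogenase, went from 34.9 ± 0.631 to 14.9 ± 2.62, carbonic anhydrase 9 (Car9) from 16.3 ± 0.418 to 8.84 ± 0.777 and the mitophagy gene Bnip3 from 155 ± 6.63 to 76.0 ± 11.7. Of 24 cell cycle genes, 13 fell and 0 rose, 18 and 0 adjusted over the list alone, among them the cyclins Ccnb2 (49.0 ± 2.33 to 26.1 ± 4.48) and Ccna2 (42.9 ± 1.35 to 25.8 ± 5.06). The camera adjusted p was 5.77e-05 for glycolysis, 3.16e-05 for hypoxia response and 1.04e-05 for cell cycle. With an estimated correlation these became an adjusted p = 0.657 for glycolysis, an adjusted p = 0.237 for hypoxia response and an adjusted p = 0.657 for cell cycle. Pgk1, Hk2, Slc2a1 and Ldha are on both the glycolysis and the hypoxia list, and of these Pgk1 and Hk2 fell. P4ha2, which also fell, is on both the hypoxia list and the list of proline metabolism and transport.

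Other genes with the largest decreases were the iron-carrier-binding lipocalin Lcn2 (24.0 ± 3.62 to 6.65 ± 1.42 FPKM), the neurofilament genes Nefl (40.1 ± 2.60 to 12.2 ± 0.812) and Nefm, the peptide hormone gene Apln (19.0 ± 1.28 to 5.66 ± 1.40), the interleukin 1 receptor antagonist Il1rn and the haptoglobin gene Hp (32.3 ± 1.85 to 11.3 ± 2.61). Tigit, known as a lymphocyte receptor, went from 5.34 ± 0.797 to 1.27 ± 0.473, while 1 of 17 T and NK cell markers, the chemokine Ccl5, reached a mean of 1 FPKM. All of these passed with an adjusted p between 6.25e-05 and 0.000886.

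**Figure D2:**
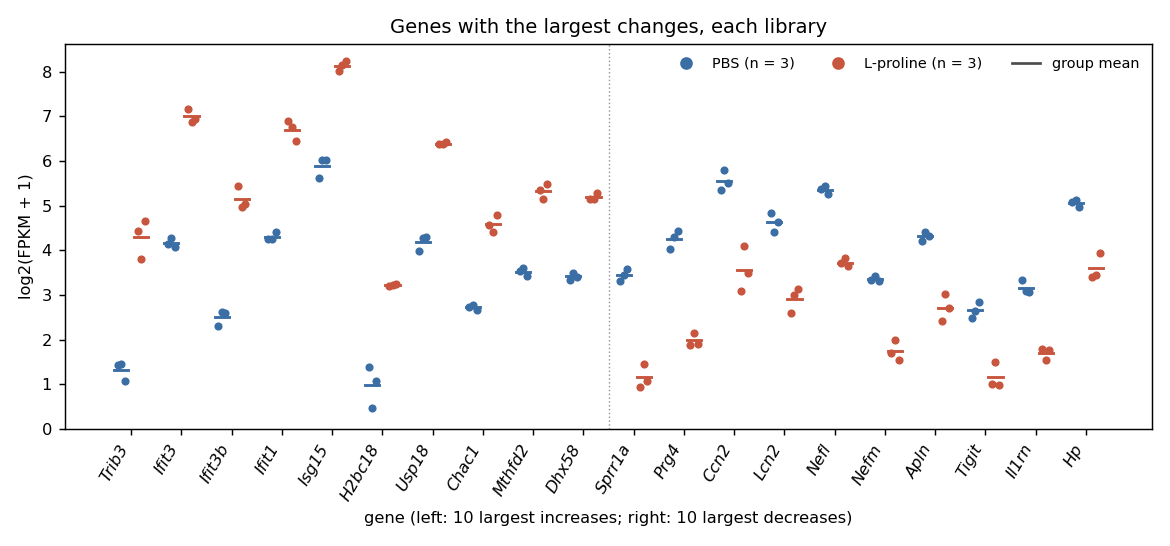
log2(FPKM + 1) in each of the 6 libraries for the 10 genes with the largest increase and the 10 with the largest decrease; points are libraries and bars are means of 3. The 3 L-proline values lie on the same side of the 3 PBS values for each of the 20 genes, because the rule that chose them required it.

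For ferroptosis, single genes moved in both directions and no list passed. Of 32 driver genes, 4 rose and 4 fell, 4 and 5 adjusted over the list alone: Chac1, Cyb5r1 (0.47 ± 0.08), Sat1 (0.49 ± 0.08) and Hmox1 rose, and Alox5, a lipoxygenase gene, had the largest decrease at -0.59 ± 0.09 on the log2 scale. The other 3 that fell, Fads1, Hilpda and Elovl5, and Hmox1 are outside the list examples and are named after their values were seen. Of 33 suppressor genes, 5 rose and 8 fell, 7 and 10 adjusted over the list alone; the metallothionein Mt2 went from 169 ± 31.1 to 65.7 ± 5.35 FPKM and glutathione synthetase (Gss) from 16.6 ± 0.456 to 28.7 ± 3.34. The camera adjusted p was 0.908 for drivers and 0.744 for suppressors, and the median log2 fold changes were -0.09 and -0.13. Ferritin heavy chain (Fth1) rose from 3064 ± 121 to 4160.1 ± 249 FPKM, a log2 fold change of 0.44 ± 0.07 (adjusted p = 0.00499), which fell to 0.10 with quantile normalization (adjusted p = 0.286; 0.000419 to 0.286 over the alternatives). The light chain Ftl1 was 2519 ± 215 and 2473 ± 146. The lipid peroxide reductase Gpx4 was 226 ± 13.1 and 264 ± 19.99 (adjusted p = 0.0817), Acsl4 40.7 ± 6.33 and 31.1 ± 9.61 (0.202), the transferrin receptor Tfrc 12.2 ± 0.358 and 7.95 ± 2.78 (0.0816) and Aifm2 9.42 ± 0.159 and 7.70 ± 0.554 (0.0541). Without L-proline 1 the adjusted p became 0.0405 for Gpx4, 0.0261 for Acsl4 and 0.0196 for Tfrc, and without L-proline 3 it became 0.0435 for Tfrc and 0.0411 for Aifm2. Over all alternatives it ran from 0.00625 to 0.269 for Gpx4, 0.0130 to 0.478 for Acsl4, 0.00852 to 0.207 for Tfrc and 0.00986 to 0.225 for Aifm2. The cystine transporter Slc7a11, at 0.226 ± 0.111 and 0.625 ± 0.278 FPKM, lay under the filter on low values and was not tested. It was still detected, with 110, 89 and 35 fragments in PBS 1, 2 and 3. L-proline 1, 2 and 3 had more, at 326, 150 and 163.

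Hmox1, the heme oxygenase gene, and Ptgs2, used as a marker of ferroptosis, passed narrowly, and the groups overlapped for both. Hmox1 went from 79.8 ± 17.9 to 142 ± 36.7 FPKM (log2 fold change 0.81 ± 0.21, adjusted p = 0.0336). Its adjusted p was 0.0828 without PBS 2, 0.123 without PBS 3, 0.0939 without L-proline 3, 0.0597 with no filter and 0.0501 with equal sums (0.0120 to 0.123 over the alternatives). Ptgs2 went from 38.5 ± 9.41 to 20.8 ± 7.58 (-0.89 ± 0.25, adjusted p = 0.0452), and its adjusted p was 0.149 without PBS 1, 0.141 without PBS 3, 0.124 without L-proline 2, 0.112 without L-proline 3, 0.0761 with no filter, 0.0580 without the mitochondrial and 20 most abundant genes and 0.0511 with the robust variance model (0.000783 to 0.149 over the alternatives). Of 24 iron handling genes, 2 rose (Fth1, Hmox1) and 1 fell (Lcn2), the same numbers adjusted over the list alone; camera gave an adjusted p = 0.744 with a direction above other genes, while the mean and median log2 fold changes were -0.09 and -0.05.

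Pparg itself was 2.78 ± 0.265 FPKM in PBS and 2.68 ± 0.219 in L-proline, a log2 fold change of -0.04 ± 0.09 (adjusted p = 0.805). Of 18 tested PPARγ targets, 2 rose and 4 fell, 2 and 4 adjusted over the list alone. The fatty acid binding proteins Fabp5 (32.9 ± 3.42 to 16.9 ± 1.799) and Fabp4 (5.93 ± 0.400 to 2.55 ± 0.514) fell, as did Pnpla2 and Gk, chosen after their values were seen, and the lipid droplet gene Plin2 and the transporter gene Slc27a1 rose by 0.50 ± 0.09 and 0.48 ± 0.09 on the log2 scale. The list did not pass with camera (adjusted p = 0.603), while fry, which does not compare a list with other genes, gave an adjusted p = 0.0181 for a net decrease and passed 14 lists in all; the median of the list, -0.09, was 0.01 with quantile normalization. For PPARα and fatty acid oxidation 2 of 27 genes rose and 8 fell, 5 and 10 adjusted over the list alone (camera adjusted p = 0.435), with Ucp2 at -0.86 ± 0.10 and Acot2 at 0.88 ± 0.12 on the log2 scale. Ppard was 24.4 ± 1.14 and 25.9 ± 2.67, and Ppara did not exceed 0.0652 FPKM in any library.

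Among genes of proline metabolism and transport, 2 of 16 fell and 0 rose, and adjusted over the list alone 6 fell and 3 rose. Those that fell were the prolyl hydroxylase subunits P4ha3 (23.5 ± 1.52 to 15.1 ± 0.593 FPKM) and P4ha2 (92.8 ± 3.32 to 62.7 ± 6.34), which act on collagen. The synthesis gene Aldh18a1 was 30.9 ± 2.73 and 37.6 ± 2.31 (adjusted p = 0.0582, 0.0404 with median-of-ratios scaling and 0.0318 with quantile normalization; 0.00366 to 0.207 over the alternatives). It was 0.0452 without PBS 2 and 0.0346 without L-proline 1. Pycr1, Oat and Aldh4a1 had log2 fold changes of 0.18, 0.07 and 0.21 and did not pass. Prodh, the first enzyme of proline breakdown, was 0.550 ± 0.0228 and 0.254 ± 0.0658 FPKM, under the filter, and was not tested. Its fragments numbered 52, 46 and 50 in PBS 1, 2 and 3. They were fewer in L-proline 1, 2 and 3, at 18, 28 and 21. Prodh2 was not listed in the table used here. The camera adjusted p of the list was 0.891.

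**Figure D3:**
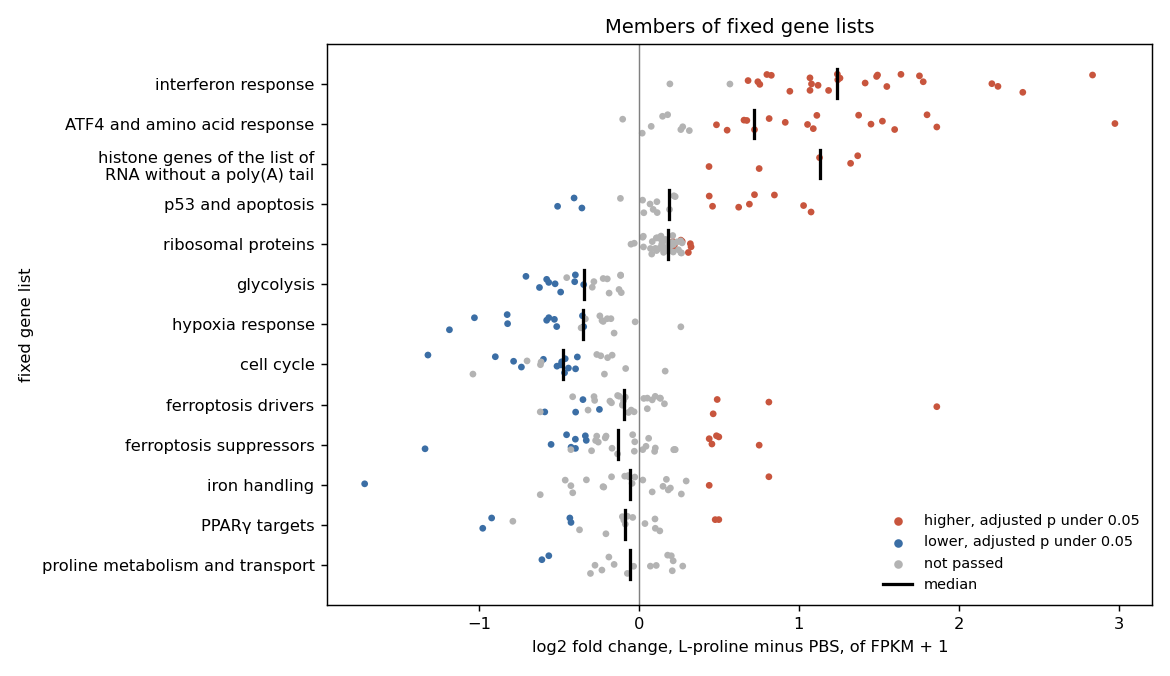
log2 fold change (L-proline minus PBS, of FPKM + 1) of each tested member of 13 fixed gene lists; red and blue points passed an adjusted p under 0.05, and black bars are medians. Interferon and ATF4 genes lie to the right with medians of 1.24 and 0.72, and the ferroptosis, iron, PPARγ and proline lists have medians between -0.13 and -0.05.

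Genes of heart stress and of the heart muscle could be judged only in part, given the low heart muscle transcripts in every library. Of 6 tested cardiac stress genes, 1 rose and 2 fell, 1 and 3 adjusted over the list alone: the secreted stress factor Gdf15 went from 16.3 ± 0.413 to 44.2 ± 6.59 FPKM, and Ccn2 and the ankyrin repeat gene Ankrd1 fell, the latter from 222 ± 13.01 to 86.5 ± 15.0 (camera adjusted p = 0.744). Nppb was 0.781 ± 0.312 and 0.124 ± 0.108 FPKM, Nos3 0.157 ± 0.0316 and 0.129 ± 0.0425, and both lay under the filter. Myh7 was listed at 0 in the 3 PBS libraries and at no more than 0.0123 in the L-proline libraries, and Nppa was not listed in the table used here. Of 7 tested sarcomere and calcium handling genes, Tnnt2 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.744).

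Genes of the extracellular matrix moved in both directions. Of 28 collagen and matrix genes, 10 rose and 8 fell, 12 and 9 adjusted over the list alone. The lysyl oxidase Loxl2 (12.7 ± 0.500 to 6.94 ± 0.221 FPKM), the latent TGF-beta binding protein Ltbp2 (33.3 ± 2.09 to 15.8 ± 2.13), the protease inhibitor Timp1 (487 ± 32.5 to 268 ± 27.1) and Ccn2 fell. The mean log2 fold change was -0.06, the median was 0.11 and camera placed the list above other genes without passing (adjusted p = 0.312). Of 10 tested fibroblast markers, 4 rose and 2 fell, 6 and 2 adjusted over the list alone: dermatopontin (Dpt) went from 1.37 ± 0.137 to 5.42 ± 0.469, the collagens Col3a1 from 1226 ± 18.5 to 1824 ± 150.1 and Col1a2 from 615 ± 18.2 to 798 ± 55.7, and the surface antigen gene Cd248 fell. Camera gave an adjusted p = 0.00772 for the fibroblast markers and an adjusted p = 0.379 with an estimated correlation; it was 0.0890 at a mean FPKM of at least 5 and 0.0514 with ranks. These changes were seen in libraries whose heart muscle genes Ttn and Ryr2 did not exceed 0.0131 FPKM.

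Inflammatory genes divided between the directions, with 5 of 15 rising and 6 falling, 6 and 6 adjusted over the list alone. The chemokine genes Ccl5 (31.8 ± 0.338 to 82.4 ± 13.5 FPKM) and Cxcl10 (1.84 ± 0.390 to 6.76 ± 0.686), both also induced by interferon, rose. Lcn2 and the adhesion gene Vcam1 (75.7 ± 4.19 to 44.9 ± 1.50) fell. The secreted phosphoprotein gene Spp1, chosen after its values were seen, fell from 2761 ± 79.99 to 1312 ± 202. The mean log2 fold change was -0.05 while camera placed the list above other genes (adjusted p = 0.744), and the median, -0.003, was 0.05 with median-of-ratios scaling.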

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

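Fragments counted outside the listed genes were higher than in any PBS library in L-proline 1, at 1.39% of the library total, and in L-proline 3, at 3.90%, against at most 1.38% in PBS. These values were singled out because they are a signal in data that the comparisons did not use, above the level in the control libraries. The excess of L-proline 1 over the highest PBS library was small, and no cause was tested for either library.

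The heart muscle transcripts close to 0 were weighed with tests chosen only after the result was seen. Ttn, Ryr2, Myl2 and Tnni3 are listed, with at most 0.212 FPKM in any library, so filtering by the authors cannot account for their low values. Heart muscle genes that are not listed, such as Myh6, cannot be judged in this way. All fragments outside the listed genes were 1.20% to 3.90% of a library total. The same highest value, 0.212 FPKM, came from a PBS library, which argues against L-proline as the cause. The median of the fibroblast markers, 27.2 FPKM, was 0.691 times the highest of the endothelial, macrophage and pericyte and smooth muscle medians. A mostly fibroblast-like population therefore cannot be told apart by these medians from one with smooth muscle or pericyte markers. The pericyte and smooth muscle list was added to this comparison after the values were seen. Without it the comparison had favoured a fibroblast-like population. Members of that list went both ways: Acta2 had a mean of 838 FPKM, and Myh11, Rgs5 and Vtn had group means of at most 0.0961. Muscle genes close to 0, with endothelial and macrophage medians of 0.323 and 0.118 FPKM, argue against whole ventricle as the source. Tnnt2, at 32.0 ± 0.777 FPKM in PBS, was an exception. The cell cycle genes Top2a and Mki67, chosen after their values were seen, stood at 98.2 ± 13.7 and 24.7 ± 8.48 FPKM in PBS. Which cells gave the RNA, and whether they came from part of the tissue or from culture, stays open. What each difference between L-proline and PBS means for the heart depends on it.

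The higher interferon and ATF4 lists were also weighed with tests chosen only after the result was seen. The median log2 change of all tested genes was -0.0577, against 1.24 and 0.72 for the lists, which argues against a shift of all genes by scaling as the cause. Leaving out 1 L-proline library left a median of at least 0.70 in both lists, which argues against a single library. The summed rise of the macrophage genes Lyz2, Cd68, Mpeg1 and Csf1r was 2.46 FPKM, or 1.11% of the rise of Isg15, which was 221 FPKM, and this argues against RNA from admixed macrophages. A response to L-proline, the difference that the labels give between the groups, stays open as a hypothesis, since it was found and tested on the same libraries.

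For the higher histone transcripts, the tests of length and GC content and of poly(A) carry-over were chosen before their outcome was known, and the test of S phase only after the result was seen. Of 18 replication-dependent histone genes tested, 17 rose and 0 fell, with a median log2 change of 1.12 that was 0.99 after a fit on length and GC content, which argues against these as the cause. The filter admitted 8 of the 18 through their L-proline values, with PBS means under 1 FPKM; of the other 10, 9 rose with a median of 1.22, and with no filter 32 of 61 rose and 0 fell with a median of 0.48. The cell cycle list had a median of -0.47, with 13 of 24 genes falling, and so gave no sign of more cells in S phase. It cannot exclude this, because the list mixes genes of DNA replication with genes of mitosis. Among replication genes, picked out after their values were seen, Rrm2 fell (-0.60 ± 0.12). Mcm2, Mcm3, Mcm5, Mcm6 and Pcna lay between -0.61 and -0.19 without passing, and Tyms was at 0.17 and did not pass. Carry-over of RNA without a poly(A) tail cannot be told apart from a change in histone mRNA, with or without a tail. The reason is that 0 tested transcripts of that list other than histones were at hand. Fragments shared among near-identical copies were not tested.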

How the results depend on the processing

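Of the results for named and study genes under the alternatives, 624 kept their side of the threshold, 13 were weaker, 23 stronger and 0 reversed; of those for lists, 683 kept it, 15 were weaker, 14 stronger and 0 reversed. The 20 genes with the largest changes kept their calls under every alternative that tested them. They were picked from the same libraries for large changes without overlap, so this says little about other genes. Sample weights raised the passing genes to 4671 (1798 higher, 2873 lower), and the cause was not tested. Leaving out single libraries, which also leaves fewer samples, gave 874 to 2770 passing genes (366 to 965 higher, 508 to 1805 lower). The genes with unadjusted p under 0.05 and at least a 2-fold change numbered 245 with a pseudocount of 0.1, which damps low genes less, and 272 with voom, chosen after the data were seen, which passed 2038 genes. With an estimated correlation 0 lists passed, including interferon (1.32, adjusted p = 0.153) and ATF4 (0.87, adjusted p = 0.326); the cause was not tested. Fry, which does not compare a list with other genes, passed 14 lists. Those that camera did not pass were the PPARγ targets (-0.17, adjusted p = 0.0181), nitric oxide and vascular tone (0.00213), glucocorticoid response (0.00912), sarcomere and calcium handling (0.0113), ketone and fasting response (0.0181) and immediate early genes (0.0181). Ribosomal proteins (0.0990) and nuclear oxidative phosphorylation (0.530) did not pass it. The replicate block gave 2383 genes. Deviations of samples with the same number correlated at 0.651, 0.416 and -0.348, and PBS 2 correlated best with L-proline 3 (0.525), so the numbers do not show pairs. Depth limits genes near 1 fragment per kb, worth 0.0267 to 0.0286 FPKM.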

Other observations

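Vascular genes and genes of the glucocorticoid response had members that passed in both directions, and neither list passed with camera. Of 9 nitric oxide and vascular tone genes, 1 rose and 4 fell, 2 and 5 adjusted over the list alone: Apln, the nitric oxide synthase inhibitor-degrading enzyme Ddah1 (25.2 ± 1.26 to 16.8 ± 1.54 FPKM) and the inducible synthase Nos2 (36.3 ± 2.99 to 25.6 ± 3.51) fell and the endothelin gene Edn1 (3.24 ± 0.402 to 5.35 ± 0.743) rose (camera adjusted p = 0.301). Of 14 glucocorticoid response genes, 2 rose and 7 fell, 3 and 7 adjusted over the list alone (camera adjusted p = 0.0929), with Errfi1 at -1.12 ± 0.09 and Tsc22d3, a glucocorticoid-induced leucine zipper gene, at 0.98 ± 0.09 on the log2 scale. Of 23 immediate early genes, 6 rose and 8 fell, 6 and 9 adjusted over the list alone (camera adjusted p = 0.744); the transcription factors Maff (23.2 ± 0.855 to 8.59 ± 0.481) and Nr4a2 fell and the antiproliferative gene Btg2 (15.9 ± 0.773 to 34.6 ± 1.604) rose. The mesothelial markers Msln, Krt19 and Wfdc17 all fell, by 0.88, 0.93 and 0.86 on the log2 scale.

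Of 13 mitochondrially encoded genes, 3 rose and 0 fell, 3 and 0 adjusted over the list alone. Whether the list passed depended on single libraries: its mean log2 fold change was 0.33 (camera adjusted p = 0.0880), against 0.59 without L-proline 3 (2.13e-05), 0.45 without PBS 2 (0.0182), 0.54 with sample weights (0.00498), 0.22 without L-proline 1 (0.296) and 0.18 without L-proline 2 (0.363). Over the alternatives the adjusted p ran from 2.13e-05 to 0.852. ND1 went from 2275 ± 181 to 4637 ± 1200.5 FPKM and ND2 from 1210.0 ± 123 to 3093 ± 982. ND3 rose at a far lower level, from 5.85 ± 2.51 to 18.9 ± 5.89, a log2 fold change of 1.56. COX1 (0.01), CYTB (-0.12) and ND5 (-0.20) did not pass. COX1 stood at 7173 ± 516 FPKM in PBS, and why levels within the list differed so widely was not tested. Of the other lists, with the camera adjusted p, the unfolded protein response had 1 of 20 genes rising and 4 falling (0.144), sterol and fatty acid synthesis 1 of 25 and 3 (0.249), heat shock proteins 3 of 17 and 1 (0.331), the TCA cycle 1 of 23 and 3 (0.435), the ketone and fasting response 1 of 12 and 4 (0.579) and the circadian clock 1 of 14 and 1 (0.579). Autophagy and lysosome had 1 of 18 rising and 2 falling (0.744), branched chain amino acid breakdown 0 of 19 and 0 (0.744), NRF2 targets 3 of 21 and 3 (0.891), and pericyte and smooth muscle markers 1 of 8 and 1 (0.908). Both tested metallothioneins fell. Cd74, the 1 tested gene of MHC II antigen presentation, rose from 3.17 ± 0.240 to 5.62 ± 1.43 FPKM, and 0 of 2 tested cardiac ion channel genes passed.

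Lars2, a mitochondrial leucyl-tRNA synthetase gene, was backed by 7015, 5036 and 5677 fragments in PBS 1, 2 and 3. In L-proline 1, 2 and 3 it was backed by 6088, 8221 and 98394 (limma, adjusted p = 0.2502). The high value was in L-proline 3 alone, the library with the largest share of fragments outside the listed genes, 3.90%. Whether it reflects expression of Lars2 was not tested. Ifnb1, the interferon beta gene, had 0 fragments in each PBS library and 6, 2 and 7 in the L-proline libraries. Both genes were chosen after their values were seen.

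Among the 10 splits of the 6 libraries into 3 and 3, the real one gave 2056 passing genes and the highest other gave 0, so 1 split was as large; for unadjusted p with a 2-fold change these were 147 and 9, again 1 split. The real split gave 10 lists and the highest other 12, and 7 splits gave at least 10. With 10 splits the share cannot go under 0.05.

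4 lists were written after the first results were seen and each was compared with 10000 random lists of the same size and similar mean expression. Such random lists make no allowance for genes that move together. Cytosolic tRNA synthetases, known targets of ATF4, may share the rise of the ATF4 list: 10 of 20 rose and 0 fell, with a median log2 change of 0.37, above 100% of random lists (camera p = 2.35e-08, and p = 0.0750 with an estimated correlation), led by Aars (20.2 ± 2.44 to 49.6 ± 4.93 FPKM). Mitochondrial tRNA synthetases had a median log2 change of 0.0347, above 92.7% of random lists, which decided neither way. For genes driven by the co-activator YAP other than Ccn2 and Ankrd1 the median was -0.16, above 3.34% of random lists, which missed the limit of 2.5% set for it. Outputs of the MAPK pathway other than Dusp6 might fall together: 8 of 13 fell, among them Etv4 (9.43 ± 0.658 to 4.12 ± 0.388), and 1 rose. Their median was -0.48, above 0% of random lists (camera p = 0.0615 with an estimated correlation). That median is the value of Ccnd1, which also fell in the cell cycle list, so this result is not separate from the decreases given there.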
